A study of Mus musculus with 24 samples.

How the data were processed

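Total RNA from whole-thickness pieces of the mouse gastrointestinal tract was measured on 24 Affymetrix arrays. The labels place the arrays in 8 groups of 3: corpus of the stomach, jejunum, descending colon and rectum, each from conventional mice, which carry a microbiota, and from germ-free mice, which carry none. Per the labels, the corpus is the stomach without the antrum, and the descending colon and rectum are adjoining pieces of the last part of the gut. Each array has a number from 1 to 3 within its group. The labels describe the 4 regions as dissected from each mouse, but they do not state that equal numbers mark the same mouse.

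The deposited table holds a linear signal intensity for 12488 probe sets on each array. The mean of the middle 96% of probe sets lay between 200.1 and 200.14 on every array, a ratio of 1.00018, so the deposited signal values were taken to have been scaled by the authors to a common trimmed mean. The signal algorithm, the software and the detection calls were not given in the sources used here. No value column was left unmatched to a sample. Probe sets were named through the platform annotation supplied with the table: 10855 listed 1 gene, 396 several and 1237 none. Of those with 1 gene, 10839 matched the reference gene table by Entrez identifier and 0 changed symbol. No gene was named from a probe set with several genes.

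No further scaling was applied. Signals under 21.2, the 25th percentile of all values, were set to that floor, and log2 was taken. A fold is therefore on the floored scale, and it is written as "at least" where the lower group lay at the floor on all its arrays. Probe sets were tested when their signal was above 51.5, the 40th percentile, on at least 3 arrays, and the 66 control probe sets were left out. This left 9033 probe sets, of which 8101 had 1 gene, covering 6650 genes. Probe sets of one gene were kept apart and were not averaged. Probe sets for immunoglobulin, defensin, Sprr2, Reg3 and serum amyloid A genes can bind RNA of several family members, so their gene names are uncertain.

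Differences were fitted with limma 3.58.1 in R 4.3.3 with statmod 1.5.0, with a mean for each of the 8 groups and a moderated variance with an intensity trend. All p-values were two-sided, adjusted by the Benjamini-Hochberg method over the 9033 probe sets, and called at an adjusted p under 0.05. Signals are given as mean ± SD over arrays and log2 differences as estimate ± SE. Germ-free minus conventional was tested in each region and as the mean over the 4 regions. A moderated F test asked whether the status effect differed between regions. Neighbouring regions were compared in conventional mice. The number of arrays limits the precision. Nothing in the labels says which arrays share a mouse, so p-values measure the spread between these arrays.

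For each status comparison the genes named were the 12 with the largest positive and the 12 with the largest negative difference past the threshold, from probe sets with 1 gene. In a single region all 3 germ-free arrays also had to lie on one side of all 3 conventional arrays, which chance gives for 10% of probe sets. Where fewer than 20 passed, the probe sets of lowest p were added up to 20. Regional comparisons named 6 each way, the interaction the 12 of lowest p, and each gene list up to 4 members of lowest p. Reg3g, Reg3b, Pigr, Fabp1, Aqp8, Angptl4, Igha and Jchain were always given for status comparisons. In addition, 43 gene lists were fixed, and those with at least 5 measured genes were tested with camera in limma at its preset correlation of 0.01, with adjustment over the lists of a comparison. Each was repeated with an estimated correlation and with the rotation test fry. These choices were made before the data were examined.

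The arrays were checked for region markers, RNA quality and closeness to each other. Markers of region opposed the labels of 3 libraries, which stayed in the comparisons under their labels. Each comparison was also run without them, without 4 and without 5 libraries, an alternative chosen after seeing the data. Other alternatives covered scaling, floor, filter, variance model, pairing by number, the arrays in the fit and leaving out each array in turn. The steps were tested on simulated data with the jejunum comparison's spread and 9033 probe sets, 200 of them changed: 31 of 100 changes of 1 on the log2 scale and 80 of 100 changes of 2 were recovered, with 4 false calls.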

Results

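Expression was measured in whole tissue from 4 regions of the mouse gut, the corpus of the stomach, the jejunum, the descending colon and the rectum, in conventional and germ-free mice, with 3 arrays in each of the 8 groups. The comparisons ask how transcript levels along the tract differ between mice with and without a microbiota, and how neighbouring regions differ in conventional mice. Median signals of the 24 arrays ran from 68.6 to 103.5, and 17.6% to 28.5% of probe sets on an array lay at or under the floor of 21.2. Signals of the 3' probe set over the 5' probe set ran from 0.626 to 0.994 for Gapdh and from 1.06 to 1.43 for actin. The highest signal of Xist, a transcript of the inactive X chromosome, was 17.5, under the floor.

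Region markers separated most libraries into corpus, jejunum and the last part of the gut by their labels. The markers given here do not tell descending colon from rectum, so those labels were not checked against each other. Atp4a, a subunit of the gastric proton pump, reached 7435 to 14479 in the corpus libraries apart from 1, and Apoa4, an apolipoprotein of fat absorption, reached 5207 to 12194 in the jejunum libraries apart from 1. Hoxb13, a homeobox gene of the hindgut, was at 989 to 1728 in the descending colon and rectum libraries apart from 2. The library labelled conventional jejunum 3 had Apoa4 at 13.8, Hoxb13 at 1626 and Car1, a colonic carbonic anhydrase, at 3290. The library labelled conventional rectum 1 had Hoxb13 at 41.7, Car1 at 5.3, Apoa4 at 2766 and the antimicrobial lectin Reg3g at 6038. The library labelled germ-free corpus 3 had Atp4a at 176, Hoxb13 at 1399 and Car1 at 1828. Markers of other tissue were also present in part elsewhere. Germ-free rectum 1 had Atp4a at 1968, and germ-free descending colon 1 had Hoxb13 at 112 and Fabp2, a fatty acid binding protein of enterocytes, at 4005. Germ-free jejunum 3 had Atp4a at 874 and Atp4b, the other proton pump subunit, at 401, against at most 10.1 for Atp4b in germ-free jejunum 1 and 2. Germ-free corpus 1 had the skeletal muscle actin Acta1 at 3289. All libraries stayed under their labels below, and values "without 3 libraries" leave out the 3 whose markers opposed their labels, a choice made after seeing the data.

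**Figure D1:**
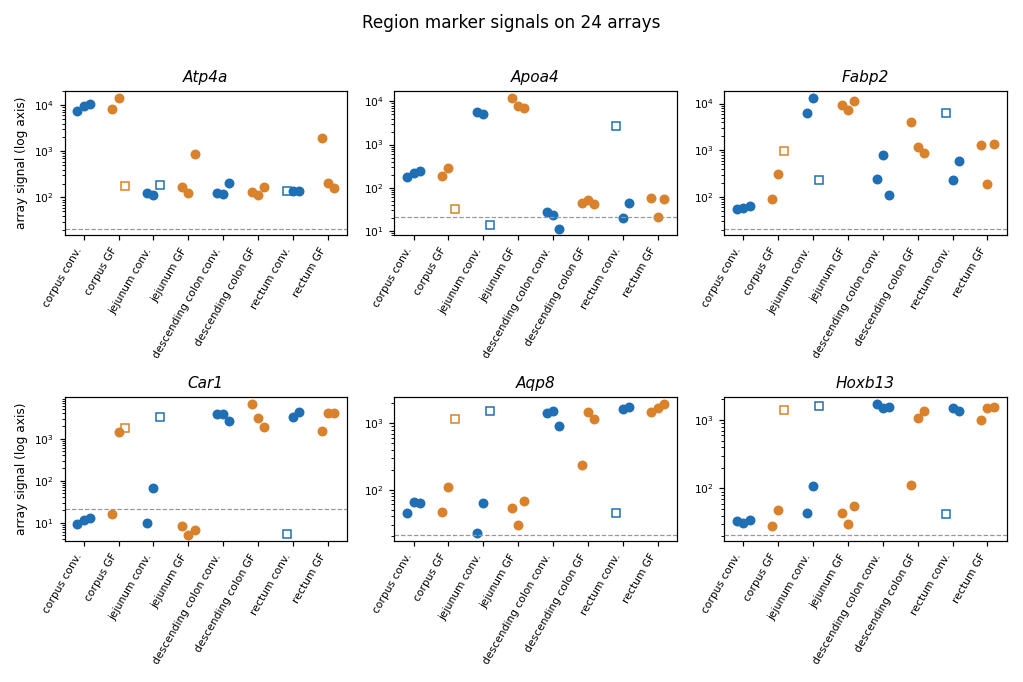
Signal of 6 region marker genes (Atp4a, Apoa4, Fabp2, Car1, Aqp8 and Hoxb13) on a log axis on each of the 24 arrays, 3 per labelled group, blue for conventional (conv.) and orange for germ-free (GF) mice. Open squares are the 3 libraries whose region markers opposed their labels and the dashed line is the floor of 21.2. Atp4a, for example, stands at 176 in the library labelled germ-free corpus 3 and at 7435 or above in the other corpus libraries.

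In conventional mice Zg16, a goblet cell lectin, was 365-fold higher in the jejunum than in the corpus, at 8486 ± 2009 (SD, n = 3) against 14.5 ± 10.9 (adjusted p = 3.13e-05). The phospholipase Pla2g2a, a Paneth cell product, was 293-fold higher (8488 ± 5971 against 14.4 ± 10.6), and the goblet cell peptides Tff3 and Retnlb were 168-fold and at least 268-fold higher. Muc3, a membrane mucin, was at least 213-fold higher, and the claudin Cldn7 134-fold higher. The jejunum group held the library labelled conventional jejunum 3, and without 3 libraries Pla2g2a was 491-fold higher. Lgals7, a keratinocyte galectin, was at least 336-fold lower in the jejunum (9.27 ± 3.87 against 7172 ± 1059). Crct1 was at least 267-fold, Krtdap 259-fold, Sprr3 239-fold and Krt13 228-fold lower. Atp4b was at least 292-fold lower in the jejunum (adjusted p = 0.00127).

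By limma, 1694 probe sets differed between jejunum and corpus, 709 higher and 985 lower in the jejunum. Of the fixed lists, squamous epithelium fell as a group in the jejunum, with 24 of 34 measured members lower and 0 higher over all probe sets, and 25 lower when adjusted over the list alone (camera adjusted p = 1.87e-15; adjusted p = 0.305 with an estimated correlation). Gastric gland markers had 16 of 21 members lower, 17 adjusted over the list alone (adjusted p = 2.03e-08; adjusted p = 0.305 with an estimated correlation). Brush border enzymes and enterocyte markers had 15 of 27 higher and 0 lower, with 18 higher and 1 lower adjusted over the list alone (adjusted p = 7.12e-09; adjusted p = 0.305 with an estimated correlation). Goblet cell genes and mucins had 9 of 20 higher and 2 lower, with the same counts adjusted over the list alone (adjusted p = 0.000194; adjusted p = 0.343 with an estimated correlation). Smooth muscle had 15 of 19 lower, 17 adjusted over the list alone (adjusted p = 7.62e-07; adjusted p = 0.343 with an estimated correlation). The count was 1048 without conventional corpus 3, 1055 without conventional jejunum 1 and 1017 without conventional jejunum 2. Without 3 libraries it was 2333, of which 1603 were also called with all libraries, and leaving out libraries that look like another region raises regional differences by construction.

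Between descending colon and jejunum of conventional mice, limma called 0 probe sets, with 989 at an unadjusted p under 0.05, in a jejunum group that held the library with hindgut markers. Without conventional jejunum 3 alone the count was 540, and without 3 libraries it was 1039, 582 higher and 457 lower in the colon, with 2 jejunum libraries left. In those 21 libraries Apoa4 was 229-fold lower in the colon, at 20.4 ± 8.07 (n = 3) against 5418 ± 299 (n = 2; adjusted p = 4.24e-11), and with all libraries its difference was -5.18 ± 1.63 (SE; adjusted p = 0.4). Apoa1, an apolipoprotein, was 218-fold lower and the brush border peptidase Enpep 88.4-fold lower. The bile acid exporter subunit Slc51a was 90.0-fold lower and Reg3g 115-fold lower in the 21 libraries. Car1 was 91.7-fold higher in the colon (log2 difference 6.52 ± 1.03 SE; adjusted p = 0.000221), and Car2, another carbonic anhydrase, was 48.1-fold higher. Wfdc2, a secreted protease inhibitor homologue, was at least 68.9-fold higher. Apoa4 and Car1 were among the markers that put libraries in doubt. The differences in the 21 libraries, lists included, are therefore raised by construction. Without 3 libraries, amino acid, peptide and sugar uptake genes had 12 of 20 members lower and 3 higher, with 14 lower and 3 higher adjusted over the list alone (adjusted p = 4.65e-08; adjusted p = 0.000896 with an estimated correlation). Colonocyte markers had 9 of 17 higher and 1 lower, with the same counts adjusted over the list alone (adjusted p = 1.86e-07; adjusted p = 0.0369 with an estimated correlation).

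Rectum and descending colon of conventional mice differed at 1 probe set, 1 of the 2 tested for Urod, an enzyme of heme synthesis. Its signal was 16.9 ± 2.98 (n = 3) in the rectum, at the floor on all arrays, and 83.0 ± 3.00 in the descending colon, at least 3.91-fold lower in the rectum (limma adjusted p = 0.00442). At an unadjusted p under 0.05 there were 168 probe sets. The rectum group held the library labelled conventional rectum 1, whose markers opposed its label. Without 3 libraries, with 2 rectum libraries left, the same probe set was called and 113 had an unadjusted p under 0.05. The call was absent with the floor at the 40th percentile or the filter at the 60th.

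In the jejunum, genes that rose in germ-free mice included Fabp1, Ppara, Pex11a and Slc5a11, and genes that fell included Cd53, Nfkbiz and Cyba. Fabp1, a fatty acid binding protein, rose 14.8-fold, to 1114 ± 1100 (SD, n = 3) from 87.0 ± 120 (log2 difference 3.89 ± 0.68 SE; adjusted p = 0.0106). Fabp1 lay under the floor in the library labelled conventional jejunum 3, and without 3 libraries it was 9.15-fold higher (3.19 ± 0.67; adjusted p = 0.0349). Ppara, the nuclear receptor for fatty acids, rose 3.60-fold (567 ± 202 against 160 ± 57.4; adjusted p = 0.0231), and Pex11a, a factor of peroxisome division, rose 2.40-fold (347 ± 38.5 against 144 ± 10.6; adjusted p = 0.000438). Slc5a11, a sodium and myo-inositol cotransporter, rose 6.54-fold (162 ± 56.4 against 23.2 ± 4.68; adjusted p = 0.000107). Among the genes that fell, the leukocyte tetraspanin Cd53 was 5.75-fold lower (15.9 ± 10.3 against 143 ± 75.6; adjusted p = 0.0444), and Nfkbiz, a regulator of the NF-kB response, 3.20-fold lower (116 ± 43.8 against 367 ± 102; adjusted p = 0.016). Cyba, a subunit of the phagocyte NADPH oxidase, fell 2.49-fold (465 ± 129 against 1134 ± 155; adjusted p = 0.0332).

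Ddx6, an RNA helicase, rose 6.85-fold (adjusted p = 0.00769), Bach1, a heme-regulated repressor, at least 4.84-fold (adjusted p = 0.0332), and Fst, an activin-binding protein, at least 4.67-fold (adjusted p = 0.0103). Ago2, the kinase genes Wnk1 and Csnk2a1, the caspase-8 regulator Cflar and the transcription factor Nfatc3 rose between 2.88-fold for Nfatc3 and 3.61-fold for Ago2. Ckap4, a protein of the endoplasmic reticulum, fell at least 4.08-fold (log2 difference -2.03 ± 0.24 SE; adjusted p = 0.000192). Probe sets named for Sprr2c-ps and Sprr2e, of the small proline-rich family, fell 5.44-fold and 2.69-fold. The leukocyte actin-binding protein Lsp1 fell 3.12-fold, the integrin adaptor Apbb1ip 2.53-fold, the signalosome subunit Cops2 3.20-fold, and the cytoskeletal genes Actn1 and Septin7 2.57-fold and 2.49-fold. The Urod probe set that differed between rectum and colon fell 4.15-fold (19.9 ± 7.67 against 100.2 ± 39.6; adjusted p = 0.000599).

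**Figure D2:**
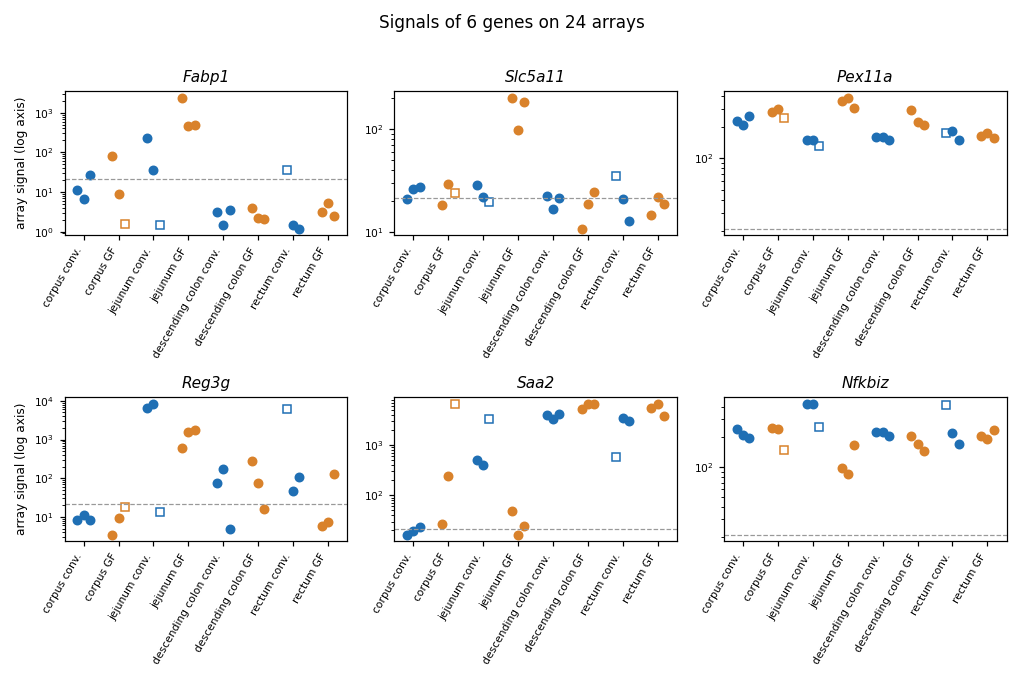
Signal of 6 genes (Fabp1, Slc5a11, Pex11a, Reg3g, Saa2 and Nfkbiz) on a log axis on each of the 24 arrays, 1 point per array and 3 per labelled group, blue for conventional (conv.) and orange for germ-free (GF) mice. Open squares are the 3 libraries whose region markers opposed their labels and the dashed line is the floor of 21.2. With all libraries Fabp1, Slc5a11, Pex11a and Nfkbiz passed the test in the jejunum, and Saa2 and the plotted probe set of Reg3g did not (adjusted p = 0.0776 and 0.994). Slc5a11 averaged 162 in germ-free and 23.2 in conventional jejunum libraries.

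Genes of fatty acid oxidation and PPAR alpha targets rose as a group in the germ-free jejunum: 2 of 24 measured members rose over all probe sets, Pex11a and Fabp1, and 4 adjusted over the list alone (camera adjusted p = 1.69e-06; adjusted p = 0.192 with an estimated correlation). Acaa2, the last enzyme of mitochondrial beta-oxidation, was at 5400 ± 881 (n = 3) against 2193 ± 495 (adjusted p = 0.0818). Xenobiotic metabolism genes were also higher as a group, with 0 of 55 past the threshold over all probe sets and 0 adjusted over the list alone (adjusted p = 0.000781; adjusted p = 0.132 with an estimated correlation). Its members of lowest p were the cytochromes Cyp4b1, 2228 ± 781 against 540 ± 290, and Cyp2b10, 1117 ± 875 against 253 ± 194. Oxidative phosphorylation genes were higher in 37 of 45 cases, with 0 past the threshold and 3 adjusted over the list alone (adjusted p = 7.66e-06; adjusted p = 0.591 with an estimated correlation). The complex III subunit Uqcrh, for one, was at 2968 ± 169 against 2122 ± 101. Amino acid, peptide and sugar uptake genes had 0 of 20 past the threshold, with 4 higher and 1 lower adjusted over the list alone (adjusted p = 0.000969; adjusted p = 0.671 with an estimated correlation). Brush border enzymes had 0 of 27 past the threshold and 0 adjusted over the list alone (adjusted p = 0.00539; adjusted p = 0.732 with an estimated correlation), with lactase, Lct, at 3748 ± 1971 against 685 ± 659. The library labelled conventional jejunum 3 had Apoa4 at 13.8 and Fabp2 at 226. Without 3 libraries the brush border list did not pass (adjusted p = 0.236), and the log2 difference of Lct was 1.83 in place of 3.66.

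Immune lists were lower in the germ-free jejunum at the preset correlation only. B and plasma cell genes had 0 of 17 past the threshold and 0 adjusted over the list alone (camera adjusted p = 0.0031; adjusted p = 0.732 with an estimated correlation). A probe set named for Ighg3 in that list was at 75.0 ± 32.4 (n = 3) against 892 ± 425. MHC class II genes had 0 of 12 past the threshold and 0 adjusted over the list alone (adjusted p = 0.0143; adjusted p = 0.732 with an estimated correlation). Its members included H2-DMb1, 134 ± 20.8 against 428 ± 245, and Cd74, 1355 ± 195 against 3679 ± 1612. The interferon response list had 0 of 22 past the threshold and 0 adjusted over the list alone (adjusted p = 0.00468; adjusted p = 0.732 with an estimated correlation). Colonocyte markers were lower as a group (adjusted p = 0.0185; adjusted p = 0.732 with an estimated correlation), with 0 of 17 past the threshold and 0 adjusted over the list alone, beside a level of Car1 of 3290 in the library labelled conventional jejunum 3. Without 3 libraries this list did not pass (adjusted p = 0.451).

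In all, limma called 42 probe sets in the jejunum, 20 higher and 22 lower in germ-free mice. The count was 22, 17 and 10 without conventional jejunum 1, 2 and 3, and 12, 19 and 265 without germ-free jejunum 1, 2 and 3, the last being the library with Atp4a at 874. Of 24 named genes, 7 kept their call whichever of the 6 libraries was left out: Slc5a11, Ddx6, Csnk2a1, Nfatc3, Pex11a, Ckap4 and Urod. Fabp1 lost its call without conventional jejunum 2 or 3 or germ-free jejunum 1 (highest adjusted p = 0.103), and Ppara without conventional jejunum 3 or germ-free jejunum 1 (highest adjusted p = 0.145). Nfkbiz lost it without conventional or germ-free jejunum 1 or 2 (highest adjusted p = 0.103), and Cyba without any conventional library or germ-free jejunum 1 (highest adjusted p = 0.18). Cd53 kept its call in 1 of the 6 omissions (highest adjusted p = 0.196). After quantile normalization the split was 14 higher and 9 lower, with array medians equalised it was 20 and 10, and a fit to the 6 jejunum arrays alone called 0. The split was 34 and 18 with the floor at the 40th percentile and 18 and 25 with it at the 10th. Without the filter it was 24 and 11, and with status and number as a random block 17 and 10. Without 3 libraries 51 probe sets were called, 23 of them also called with all libraries, and 239 when germ-free jejunum 3 was put with the conventional side. Those named without 3 libraries included Saa2, an acute phase apolipoprotein, 15.4-fold lower in germ-free jejunum (30.2 ± 17.4, n = 3, against 456 ± 73.3, n = 2; adjusted p = 0.0025), and 1 probe set of Reg3g, 7.96-fold lower (adjusted p = 0.00528). The mucosal scavenger protein Dmbt1 was 3.69-fold lower, the sialyltransferase St6gal1 3.41-fold, and the MHC class II genes H2-Aa and H2-DMb1 4.72-fold and 4.08-fold lower. Tff2, a mucus peptide of the stomach, was 55.8-fold higher (1878 ± 681 against 25.6 ± 33.0; adjusted p = 0.00722), and the glutathione transferase Gsta4 4.94-fold higher. Tff2 was at 1243, 2597 and 1793 in germ-free jejunum 1, 2 and 3, and Cblif, gastric intrinsic factor, at 35.9, 38.4 and 280. The library labelled conventional jejunum 3, left out of this fold, had Tff2 at 1253. With all libraries the log2 difference of Tff2 was 4.04, against 5.80 without 3.

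Other genes fixed in advance did not pass in the jejunum with all libraries. Reg3b was at 5486 ± 725 (n = 3) in germ-free against 8637 ± 8253 in conventional libraries, and the main Reg3g probe set at 1314 ± 641 against 4973 ± 4395 (adjusted p = 0.91 and 0.994). These means and the fitted log2 differences, 0.56 for Reg3b and 0.17 for Reg3g, point opposite ways, and without 3 libraries the differences were -1.15 and -2.65. The polymeric immunoglobulin receptor Pigr was at 6737 ± 1319 against 10562 ± 2733, Igha at 2822 ± 1040 against 7690 ± 2329 and Jchain at 575 ± 357 against 1607 ± 218 (adjusted p = 0.776, 0.657 and 0.534). The water channel Aqp8 was at 50.1 ± 18.7 against 547 ± 874, and Angptl4, an inhibitor of lipoprotein lipase, at 220 ± 54.6 against 153 ± 63.8 (adjusted p = 0.72 and 0.52). The log2 difference of Aqp8 was -1.44 with all libraries and 0.35 without 3.

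In the corpus, no single gene passed the test between germ-free and conventional mice: limma called 0 probe sets, with 817 at an unadjusted p under 0.05. The probe sets of lowest p had an adjusted p of 0.0807. Among them Zg16 was at 2937 ± 4728 (SD, n = 3) in germ-free against 14.5 ± 10.9 in conventional corpus, and Tff3 at 2873 ± 4465 against 59.2 ± 25.5, in a germ-free group that held the library with hindgut markers. The log2 difference of Tff3 was 3.84 with all libraries and 2.15 without 3. Pck1, an enzyme of gluconeogenesis, was at 164 ± 135 against 15.3 ± 11.1, and the semaphorin Sema3e at 83.6 ± 63.3 against 315 ± 28.0. Their log2 differences were 2.47 and -2.23 with all libraries and 1.83 and -1.41 without 3. Chil3, a chitinase-like protein of macrophages, was at 47.3 ± 14.4 against 413 ± 398, the signal transducer Smad4 at 499 ± 206 against 235 ± 56.7, and P4hb, a protein disulfide isomerase, at 164 ± 12.3 against 591 ± 148. Smaller differences included the homeobox gene Hlx, 79.9 ± 23.2 against 32.0 ± 10.3, Sash1, 172 ± 34.1 against 84.0 ± 6.97, and Atp6v0a1, a proton pump subunit of acidic vesicles, 164 ± 2.15 against 279 ± 33.0.

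Lists also differed in the corpus, where the germ-free group held the library labelled germ-free corpus 3. Squamous epithelium was lower in germ-free corpus, with 0 of 34 past the threshold and 0 adjusted over the list alone (camera adjusted p = 9.14e-09; adjusted p = 0.809 with an estimated correlation), and so were gastric gland markers, with 0 of 21 and 0 (adjusted p = 0.00481; adjusted p = 0.809 with an estimated correlation). Goblet cell genes and mucins were higher, with 0 of 20 past the threshold and 5 adjusted over the list alone (adjusted p = 0.0108; adjusted p = 0.809 with an estimated correlation), as Muc3 and Retnlb show with germ-free SDs of 3620 and 5325 around means of 2177 and 3217. The library labelled germ-free corpus 3 had Atp4a at 176, Car1 at 1828 and a probe set of the squamous keratin Krt13 at 61.9. Germ-free corpus 1 and 2 had Atp4a at 8185 and 14479, against 7435 to 10364 in conventional corpus. They had that Krt13 probe set at 5792 and 3613, against 3831 to 5719. The loss of these squamous and gastric markers thus lay in that library alone. Skeletal muscle genes were higher, with 0 of 23 past the threshold and 0 adjusted over the list alone (adjusted p = 0.00481; adjusted p = 0.809 with an estimated correlation), beside Acta1 at 3289 in germ-free corpus 1. Leaving out 1 library moved the count of calls from 0 to 1 without conventional corpus 3, 159 without germ-free corpus 1, 12 without germ-free corpus 2 and 4 without germ-free corpus 3. Without 3 libraries it was 6, among them Zg16, 7.92-fold higher in germ-free corpus (208 ± 145, n = 2, against 14.5 ± 10.9, n = 3; adjusted p = 0.000218), and the calcium pump Atp2a3, 6.25-fold lower (20.1 ± 3.32 against 142 ± 50.3; adjusted p = 0.000611). Of the 2 germ-free libraries left, germ-free corpus 1 had Zg16 at 105 and Car1 at 15.7, and germ-free corpus 2 had them at 311 and 1433.

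Of the genes fixed in advance, Pigr was at 3448 ± 5117 (n = 3) in germ-free and 1250 ± 728 in conventional corpus (adjusted p = 0.94). Igha was at 702 ± 499 against 3035 ± 3115, Jchain at 210 ± 134 against 680 ± 695, and Reg3b at 237 ± 84.6 against 104 ± 4.71. Aqp8 was at 441 ± 628 against 57.7 ± 10.9, Angptl4 at 154 ± 21.5 against 123 ± 10.4 and Fabp1 at 29.7 ± 42.6 against 14.7 ± 10.5 (adjusted p from 0.728 for Aqp8 to 0.833 for Fabp1). The library labelled germ-free corpus 3 had Aqp8 at 1166 and Pigr at 9355, against at most 111 and 632 in germ-free corpus 1 and 2. Reg3g lay at the floor on all 6 arrays.

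In the descending colon the same Urod probe set was the 1 called by limma, at 17.5 ± 2.11 (SD, n = 3) in germ-free and 83.0 ± 3.00 in conventional mice, at least 3.91-fold lower (adjusted p = 0.00442). At an unadjusted p under 0.05 there were 733 probe sets. The call was absent with the floor at the 40th percentile, with the filter at the 60th and in a fit to the 6 colon arrays alone. Genes next in order included Csnk2a1, 120 ± 4.56 against 49.5 ± 8.89, Ndufb3, a subunit of respiratory complex I, 999 ± 295 against 491 ± 93.2, Sac3d1, 150 ± 62.6 against 42.0 ± 39.6, and Actn1, 77.2 ± 18.5 against 187 ± 19.4 (each adjusted p = 0.113). Ddx6 was at 374 ± 46.6 against 97.4 ± 44.7 (adjusted p = 0.236), Nfatc3 at 290 ± 29.0 against 149 ± 4.63 (adjusted p = 0.335), the imprinted gene Peg3 at 91.7 ± 17.1 against 36.9 ± 7.16, and Kcnma1, a potassium channel of smooth muscle, at 168 ± 3.70 against 95.8 ± 11.5.

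Oxidative phosphorylation genes were higher as a group in the germ-free colon, in 38 of 45 cases, with 0 past the threshold and 1 adjusted over the list alone (camera adjusted p = 0.00321; adjusted p = 0.886 with an estimated correlation). Fatty acid oxidation and PPAR alpha targets were higher in 21 of 24 cases, with 0 past the threshold and 1 adjusted over the list alone (adjusted p = 0.0133; adjusted p = 0.886 with an estimated correlation). In that list Pex11a was at 241 ± 44.2 (n = 3) against 156 ± 5.62, and it was highest, at 292, in germ-free descending colon 1, which had Fabp2 at 4005. Genes of the unfolded protein response were lower, with 0 of 26 past the threshold and 1 adjusted over the list alone (adjusted p = 0.0133; adjusted p = 0.886 with an estimated correlation), Creld2 being at 179 ± 20.6 against 324 ± 22.9. B and plasma cell genes were lower, with 0 of 17 past the threshold and 1 adjusted over the list alone (adjusted p = 0.0242; adjusted p = 0.956 with an estimated correlation), Cd37 being at 28.6 ± 10.5 against 133 ± 21.1. Without conventional descending colon 2 the count of called probe sets was 3, without germ-free descending colon 3 it was 2, and without 3 libraries, none of them from this region, it was 8. With germ-free rectum 1 left out as well it was 11, and with germ-free descending colon 1 left out too it was 68, 52 higher and 16 lower. The 8 included a defensin probe set named for Defa35, 8.59-fold lower in germ-free colon (43.3 ± 3.80 against 394 ± 173; adjusted p = 0.0183), and Enpep, 5.92-fold higher (434 ± 406 against 56.6 ± 13.7; adjusted p = 0.0241), the call resting on the smaller spread that the other groups then gave. Germ-free descending colon 1 in that group had Hoxb13 at 112, Fabp2 at 4005 and Aqp8 at 233.

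Of the genes fixed in advance, Igha was at 548 ± 341 (n = 3) in germ-free and 2667 ± 1282 in conventional colon, and Jchain at 173 ± 66.6 against 740 ± 453 (adjusted p = 0.634 and 0.647). Pigr was at 8802 ± 600.3 against 9423 ± 2075, and Aqp8 at 957 ± 646 against 1283 ± 321. Reg3b was at 1452 ± 1893 against 753 ± 677, Reg3g at 123 ± 135 against 82.4 ± 82.5 and Angptl4 at 134 ± 48.1 against 124 ± 44.6 (adjusted p from 0.917 for Reg3b to 0.995 for Pigr). Fabp1 lay at the floor on all 6 arrays.

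In the rectum the Urod probe set was again the 1 called by limma, in the opposite direction: 90.0 ± 17.6 (SD, n = 3) in germ-free and 16.9 ± 2.98 in conventional mice, at least 4.19-fold higher (adjusted p = 0.00214). At an unadjusted p under 0.05 there were 315 probe sets. This call too was absent with the higher floor, the higher filter and the 6 rectum arrays alone. The next genes had an adjusted p of 0.982. They included Lrg1, a secreted glycoprotein of inflammation, at 19.5 ± 4.85 against 93.3 ± 6.97, the hypoxia-induced mitochondrial protein Higd1a at 226 ± 4.07 against 126 ± 29.1, and the replication helicase subunits Mcm5 at 275 ± 162 against 475 ± 82.2 and Mcm7 at 161 ± 26.7 against 271 ± 34.6. A probe set named for Ighm was at 35.4 ± 30.9 against 202 ± 198, and the homeobox gene Hoxa11 at 73.5 ± 9.82 against 27.8 ± 21.3.

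Oxidative phosphorylation genes were higher in the germ-free rectum in 40 of 45 cases, with 0 past the threshold and 0 adjusted over the list alone (camera adjusted p = 5.51e-05; adjusted p = 0.786 with an estimated correlation). Cell cycle genes were lower, with 0 of 45 past the threshold and 0 adjusted over the list alone (adjusted p = 0.000353; adjusted p = 0.786 with an estimated correlation). Gastric gland markers were higher, with 0 of 21 and 0 (adjusted p = 0.00202; adjusted p = 0.786 with an estimated correlation), and so was squamous epithelium, with 0 of 34 and 0 (adjusted p = 0.0064; adjusted p = 0.786 with an estimated correlation). Germ-free rectum 1 had Atp4a at 1968 and Tff2 at 1903, against 205 and 157 for Atp4a and 182 and 195 for Tff2 in germ-free rectum 2 and 3. Igha was at 1161 ± 1449 (n = 3) in germ-free against 4431 ± 3215 in conventional rectum, Jchain at 338 ± 389 against 1232 ± 972, Reg3b at 293 ± 332 against 3530 ± 4389. Reg3g was at 46.2 ± 68.6 against 2063 ± 3442, and Aqp8 at 1708 ± 249 against 1144 ± 952. Pigr was at 10680 ± 2998 against 7964 ± 221, Angptl4 at 125 ± 53.3 against 116 ± 30.4 and Fabp1 at 3.60 ± 1.42 against 12.5 ± 19.4 (adjusted p from 0.982 for Reg3g to 0.996 for Angptl4). In that conventional group, the library labelled conventional rectum 1 had Reg3g at 6038, Reg3b at 8568, Igha at 8083, Jchain at 2335 and Aqp8 at 45.3. Conventional rectum 2 and 3 had at most 104, 1482, 3182 and 859 of the first 4, and Aqp8 at 1654 and 1731.

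Averaged over the 4 regions, 12 of 49 probe sets named for immunoglobulin chains fell in germ-free mice and 0 rose. This group was drawn by gene name and is not among the gene lists fixed in advance. Its count is therefore descriptive and was not a planned test. Several of these probe sets can bind the same transcripts. Among them, that for Igkv6-14 fell by 3.15 ± 0.56 on the log2 scale (SE, 12 arrays against 12; adjusted p = 0.00716), that for Ighv3-6 by 2.82 ± 0.52 (adjusted p = 0.00803), that for Ighg3 by 2.71 ± 0.55 (adjusted p = 0.0147). That for Igkv8-19 fell by 2.41 ± 0.51 (adjusted p = 0.0209) and that for Ighm by 2.26 ± 0.49 (adjusted p = 0.0231). Each of these 5 had a negative difference in all 4 regions, and each lost its call in 2 to 4 of the 6 omissions of a number (highest adjusted p = 0.136). With status and number as a random block, those for Ighg3, Igkv8-19 and Ighm lost their calls (adjusted p = 0.0507, 0.0644 and 0.0801). That for Ighm also lost it without the filter on dim probe sets (adjusted p = 0.0506), and without 3 libraries and germ-free rectum 1 those for Ighv3-6, Ighg3 and Ighm did (highest adjusted p = 0.0737). Lrg1 fell by 1.56 ± 0.25 (adjusted p = 0.00333) and Slfn2, a regulator of lymphocyte quiescence, by 1.55 ± 0.30 (adjusted p = 0.0116). The claudins Cldn2 and Cldn4, of epithelial tight junctions, fell by 1.58 ± 0.39 and 1.14 ± 0.22 (adjusted p = 0.0405 and 0.0106). Their calls held in 1 and 3 of the 6 omissions of a number.

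Among genes that rose in the mean over regions, Ddx6 was 1.64 ± 0.23 higher on the log2 scale (adjusted p = 0.00111), Wnk1 1.37 ± 0.22 (adjusted p = 0.00351), the fructose transporter Slc2a5 1.22 ± 0.28 (adjusted p = 0.0296) and Bach1 1.18 ± 0.23 (adjusted p = 0.0115). Ago2, Sac3d1, Etl4, Rufy3, Sbno1 and Peg3 rose by 0.96 to 1.14. With 1 number left out in turn, Ddx6 kept its call in all 6 omissions and Ago2 in 5. Wnk1, Sac3d1, Rufy3 and Peg3 kept theirs in 4, Slc2a5, Bach1 and Etl4 in 2 and Sbno1 in 1. These tests take the arrays as independent, and a random block for status and number cut the calls from 152 to 37. The clock repressor Nr1d2 rose by 0.94 ± 0.24 and the clock activator Arntl fell by 0.50 ± 0.13 (each adjusted p = 0.0496), in opposite directions, and neither passed without 3 libraries (adjusted p = 0.0836 and 0.0867). Igha and Jchain, at -1.90 ± 0.59 and -1.66 ± 0.51, did not pass at their main probe sets (adjusted p = 0.106 and 0.1), while another probe set of Igha fell by 1.63 ± 0.35 (adjusted p = 0.0234). Fabp1 was at 1.04 ± 0.34, Angptl4 at 0.27 ± 0.18, Aqp8 at 0.30 ± 0.68, Pigr at -0.02 ± 0.36, Reg3b at -0.22 ± 0.63 and Reg3g at -0.65 ± 0.88 (adjusted p from 0.119 for Fabp1 to 0.987 for Pigr).

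Oxidative phosphorylation genes rose as a group over the regions: 42 of 45 were higher, 3 passed over all probe sets and 15 adjusted over the list alone (camera adjusted p = 5.65e-10; adjusted p = 0.406 with an estimated correlation). The 3 were Ndufb3, up by 0.58 ± 0.10 on the log2 scale, Uqcrh, by 0.39 ± 0.07, and Ndufb9, by 0.33 ± 0.07. Fatty acid oxidation and PPAR alpha targets had 1 of 24 past the threshold, Pex11a at 0.52 ± 0.08, and 4 adjusted over the list alone (adjusted p = 0.00974; adjusted p = 0.742 with an estimated correlation). Of the unfolded protein response list, 4 of 26 fell, and 6 adjusted over the list alone (adjusted p = 0.012; adjusted p = 0.742 with an estimated correlation). These were Creld2 by 0.52 ± 0.11, Ssr1, a part of the protein translocation site, by 0.39 ± 0.09, and the disulfide isomerases P4hb and Pdia6 by 0.87 ± 0.20 and 0.42 ± 0.10. With 1 number left out in turn, Pdia6 kept its call in 0 of 6 omissions, P4hb and Creld2 in 1 and Ssr1 in 2. B and plasma cell genes fell in 1 of 17 cases, and in 5 adjusted over the list alone (adjusted p = 0.00329; adjusted p = 0.856 with an estimated correlation). Macrophage and dendritic cell genes had 1 of 16 lower, the complement gene C1qc, which fell by 0.48 ± 0.11, and 3 adjusted over the list alone (adjusted p = 0.0311; adjusted p = 0.862 with an estimated correlation). MHC class II genes had 0 of 12 past the threshold and 0 adjusted over the list alone (adjusted p = 0.012; adjusted p = 0.856 with an estimated correlation), with H2-DMb1 at -0.78 ± 0.26. The lists were not run with status and number as a random block, which cut the probe set calls of this comparison from 152 to 37.

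The mean over regions gave 152 calls by limma, 74 higher and 78 lower in germ-free mice. Without number 1 or 2 of the conventional mice in all regions the count was 15 or 10, and without number 1 or 2 of the germ-free mice it was 639 or 22. Of 35 named genes past the threshold, Ddx6 alone kept its call in each of these omissions, numbers 3 included. With status and number as a random block, as if equal numbers were 1 mouse, 37 were called. Without 3 libraries it was 132, of which 102 were shared with the full set.

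The status effect differed between regions at 2 probe sets by limma's moderated F test, with 488 at an unadjusted p under 0.05. For Urod the differences were -1.15 in the corpus, -2.05 in the jejunum, -1.97 in the descending colon and 2.07 in the rectum (adjusted p = 1.28e-05). For Slc5a11 the difference was 2.71 ± 0.29 in the jejunum, 0.04 in the descending colon and -0.23 in the rectum (adjusted p = 0.00578), and its signal averaged under 30 in the corpus in both groups. Ckap4 and Pex11a followed (adjusted p = 0.119 and 0.186), so a difference of their effect between regions was not shown. The call of Slc5a11 was absent without number 1, 2 or 3 of the conventional mice or number 1 of the germ-free mice, with an adjusted p from 0.0107 to 0.395 over the omissions. The count was 1 without number 1, 2 or 3 of the conventional mice and 75 without number 3 of the germ-free mice. Without 3 libraries it was 7, among them Saa2 (adjusted p = 0.00858), Zg16 (adjusted p = 0.0118), Nfkbiz (adjusted p = 0.0248) and the defensin probe set named for Defa35 (adjusted p = 0.0281).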

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

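All tests of the libraries, the jejunum and the Urod probe set below were chosen only after the results were seen, and the counts over other splits in the last paragraph were planned. Groups of 3 arrays were not tested for single outlying values. Urod and Slc5a11 stood out by a test that the status effect differs between regions (adjusted p = 1.28e-05 for Urod and 0.00578 for Slc5a11). The difference of Slc5a11 was 2.71 ± 0.29 in the jejunum and between -0.23 and 0.04 in the other 3 regions.

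The libraries labelled conventional jejunum 3, conventional rectum 1 and germ-free corpus 3 had markers of another region, with Car1 at 3290, 5.3 and 1828. Admixture of other tissue was argued against, since the 50 probe sets most typical of each labelled region lay at a median of -6.14, -3.92 and -5.52 on the log2 scale from their own replicates. A swap of the first 2 is a candidate explanation, and 2 of the 2 lay nearer the partner's label: mean distance 0.298 against 0.606 for conventional jejunum 3, and 0.358 against 0.532 for conventional rectum 1. The libraries were picked by region markers, so neither the probe sets typical of a region nor the distances are independent of that choice. Conventional descending colon libraries were also nearest to conventional rectum, so which distal piece is involved stays open. Germ-free corpus 3 and germ-free descending colon 3 differed by a median of 0.0882, against 0.178 for the closest of the 275 other pairs, so they may come from 1 RNA, and no biological explanation was tested.

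In the jejunum 42 probe sets separated germ-free from conventional mice. Of these, 23 kept their call without the 3 libraries, and the 19 others had a median log2 size of 1.32 with all libraries and 1.14 without, with a median SE of 0.29 and 0.31. The library labelled conventional jejunum 3 was argued against as the sole cause, because 10 probe sets were called without it and 51 without the 3 libraries, though its part in the other calls stays open and 239 were called when germ-free jejunum 3 was put with the conventional side. More proximal tissue in the germ-free pieces is open. Without the 3 libraries 4 of 8 distal markers were lower, at a median of -0.18. Of 12 proximal markers 8 were higher and 3 lower, at a median of 0.20. Fabp1 and Tff2, both counted as proximal markers, passed by limma at 3.19 and 5.80 (adjusted p = 0.0349 and 0.00722). No distal marker passed. Unequal brightness of dim probe sets is open too, with 52.4% of the calls kept after quantile normalization at a median size ratio of 0.975. An effect of the microbiota, the difference the design names, stays open and could not be set apart from these.

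The Urod probe set split the 24 arrays into 12 and 12, with a mean of 82.0 against 19.6, and its high side held conventional arrays in 3 regions and germ-free arrays in the rectum. A change of the Urod transcript was argued against by the other Urod probe set, which differed by -0.080 between the sides. A batch of arrays along this split cannot be told apart, since 15 probe sets beside Urod passed along it by limma, against 0 along each of 6 other ways to turn whole regions, and all 15 also passed in the mean over regions. Whether material was exchanged before hybridisation cannot be told. Only 1 of the 3 doubted libraries could decide while the distal piece involved stays open. The library labelled conventional rectum 1, with 13.7, had the Urod level of its label, which chance alone gives with a probability of 0.5. The library labelled conventional jejunum 3, with 145.8, also had the level of its label. It decides only if its material is rectum, since conventional descending colon is on the high side too. What sets the Urod signal was not found.

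Other splits of the same 6 arrays were too few, at 10 each, for a share under 0.05. In the jejunum the real count was 42 and the highest other 1, with 1 of 10 splits as large. In the corpus these were 0 and 5, with 10 of 10 as large, by limma with 817 at an unadjusted p under 0.05. In the descending colon and in the rectum the real count was 1 and the highest other 0. Between jejunum and corpus they were 1694 and 1, between descending colon and jejunum 0 and 5, with 989 at an unadjusted p under 0.05, and between rectum and descending colon 1 and 0. For the mean over regions 1 of 100 drawn splits, the real one, gave 152, and the highest other was 39, so chance was excluded only for arrays taken as independent. These splits ignore mice that the regions may share, and a random block for status and number gave 37 calls. For the interaction 5 of 100 were as large as the real 2, with a highest of 11, so chance was not excluded. Splits of whole mouse numbers gave 152 and a highest other of 2 and were too few, at 10.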

How the results depend on the processing

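The runs without 3, 4 or 5 libraries were chosen after the data were seen, and all other settings were planned. Of the settings run on 259 named gene results, 4891 kept direction and side of the threshold, 398 kept direction and lost the threshold, 223 kept direction and gained it, and 53 turned direction, all of them on results not past the threshold. Of the counts, 138 stayed within 1.5 times and 65 moved. Where no cause is given below, the cause was not tested. No scaling moved the median of all genes by over 0.1 on the log2 scale. Signals near the floor limit the dim genes, and with 3 arrays a group 31 of 100 simulated changes of 1 on the log2 scale were recovered.

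Scaling changed 3 splits: quantile normalization over all arrays gave 23 calls in the jejunum, 14 higher and 9 lower, against 42 (20 and 22), and 2 in the descending colon against 1. Quantile normalization within each region also gave 2 in the descending colon. Equalised medians gave 20 higher and 10 lower in the jejunum, and 865 and 798 for jejunum against corpus, against 709 and 985. A floor at the 10th percentile gave 2 in the corpus against 0 and 1 for the interaction against 2. A floor at the 40th gave 15 in the corpus, 6 for the interaction, and 0 in the descending colon, the rectum and rectum against descending colon, each against 1. No filter gave 9 in the corpus, 5 in the descending colon, 9 for the interaction, 1 for descending colon against jejunum and 2 for rectum against descending colon. A filter at the 60th percentile, which tests fewer probe sets, gave 0 in the descending colon, the rectum, the interaction and rectum against descending colon. A variance without a trend gave 6 in the corpus. A required fold of 1.5 left 95 for the mean over regions. Fits to only the 6 arrays compared, with fewer arrays to estimate the spread, gave 0 by limma in the jejunum, descending colon and rectum. Of the gene list calls between germ-free and conventional mice, 42 at the preset correlation, 0 held with an estimated correlation and 3 by fry. Lists of the regional comparisons are not in this count.

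Without 3 libraries the counts were 6 in the corpus, 8 in the descending colon, 7 for the interaction and 1039 for descending colon against jejunum. Without 4, leaving out germ-free rectum 1 as well, they were 3, 11, 7 and 1028, and 84 for the mean over regions. Without 5, leaving out germ-free descending colon 1 too, they were 3, 68 (52 higher and 16 lower), 7 and 1066.

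Leaving out 1 array in turn, which leaves 2 in a group, gave 0 to 159 calls in the corpus, 10 to 265 in the jejunum, 1 to 3 in the descending colon and 1 in the rectum. It gave 1017 to 1920 for jejunum against corpus, 0 to 540 for descending colon against jejunum and 1 for rectum against descending colon. Leaving out 1 number in all regions gave 10 to 639 for the mean and 1 to 75 for the interaction. The lowest and highest came without conventional jejunum 3 and germ-free jejunum 3 in the jejunum, without conventional number 2 and germ-free number 1 for the mean, and the highest without germ-free corpus 1 in the corpus.

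The numbers were not taken to pair the arrays, since in no comparison were all 3 correlations of equal numbers over 0.1. In the jejunum, between germ-free and conventional arrays, they were 0.22, 0.02 and 0.06. Arrays of different status cannot share a mouse, so such correlations do not bear on a shared mouse. Between regions of 1 status the correlations had a median of 0.299 for germ-free number 3 (0.160 to 0.455). The medians were 0.231 for germ-free number 1 (0.0178 to 0.433) and 0.0603 for number 2 (-0.0499 to 0.173). For conventional numbers 1, 2 and 3 they were 0.0544 (-0.0563 to 0.615), 0.00567 (-0.497 to 0.0561) and 0.0731 (0.0491 to 0.666). A shared mouse is therefore not excluded (consensus correlation 0.12). With the number as a replicate block, limma called 48 in the jejunum, 0 in the corpus, 1 in the descending colon and 1 in the rectum. It called 204 for the mean, 2 for the interaction and 1811 for jejunum against corpus. For descending colon against jejunum it called 0, and for rectum against descending colon 1. Over the germ-free against conventional comparisons, 41 gene lists were called. This block joins germ-free and conventional arrays of equal number, so it does not model a shared mouse. A random block for each status and number gave 27 in the jejunum and 37 for the mean.

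Directions that turned were all of genes not past the threshold, and ranges are over settings with 1 array, or 1 number, left out. Pigr in the descending colon, -0.07, was 0.054 with quantile normalization over all arrays, 0.052 within each region and -0.27 to 0.035 with 1 array left out. Reg3g in the jejunum, 0.17, was -0.26 with the floor at the 40th percentile, -2.65 without 3, 4 or 5 libraries and -2.65 to 1.67 with 1 array left out, and another Reg3g probe set ran from -2.99 to 0.51. Reg3b there was -1.15 without 3, 4 or 5 libraries (-1.15 to 1.66 with 1 left out) and Aqp8 0.35 (-2.72 to 0.35). In the corpus Pigr was -1.19 without 3, 4 or 5 libraries (-1.19 to 1.16), Igha ran from -3.03 to 0.082, Jchain from -2.42 to 0.22 and Fabp1 from -0.11 to 0.84. In the descending colon, without 5 libraries, Aqp8 was 0.063 (-1.27 to 0.063 with 1 left out), Reg3b -0.39 (-0.40 to 1.55) and Reg3g -0.66 (-0.66 to 1.18), and Angptl4 ran from -0.16 to 0.38. Angptl4 in the rectum ran from -0.27 to 0.32, and was 0.52 without 4 or 5 libraries. For the mean over regions Aqp8 was -0.018 without 3 libraries (-0.47 to 0.94 with a number left out), Pigr ran from -0.46 to 0.23, Reg3b from -0.98 to 0.27 and Reg3g from -1.75 to 0.24.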

Other observations

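The values without 3 libraries in this part come from a choice made after the data were seen, and the other values from planned tests. Between conventional jejunum and corpus, lists beyond epithelium also differed. Cell cycle genes had 19 of 45 higher in the jejunum and 0 lower, with 26 higher adjusted over the list alone (camera adjusted p = 1.05e-09; adjusted p = 0.343 with an estimated correlation). Genes of MHC class I, which present peptides to T cells, had 8 of 14 higher and 10 adjusted over the list alone (adjusted p = 2.92e-05; adjusted p = 0.343 with an estimated correlation). Fibroblast and matrix genes had 22 of 37 lower and 29 adjusted over the list alone (adjusted p = 2.3e-09; adjusted p = 0.343 with an estimated correlation). Antimicrobial genes had 11 of 22 higher and 4 lower, with 12 and 4 adjusted over the list alone (adjusted p = 0.00604; adjusted p = 0.305 with an estimated correlation). A defensin probe set named for Defa23 was 77.7-fold higher in the jejunum, at 9860 ± 10345 (SD, n = 3) against 26.1 ± 9.79 (adjusted p = 0.00846). It lost its call without conventional jejunum 1 or 2 (highest adjusted p = 0.07), and without 3 libraries it was 488-fold higher (log2 difference 8.93).

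Between descending colon and jejunum without 3 libraries, brush border genes had 15 of 27 lower in the colon and 1 higher, with 17 and 2 adjusted over the list alone (adjusted p = 1.28e-10; adjusted p = 0.0148 with an estimated correlation). Fat absorption genes had 11 of 24 lower and 4 higher, with 12 and 5 adjusted over the list alone (adjusted p = 2.5e-07; adjusted p = 0.0119 with an estimated correlation). The galectin Lgals2 was 95.1-fold lower in the colon (log2 difference -6.57 ± 0.51 SE, 3 arrays against 2; adjusted p = 2.5e-08). Fibroblast and matrix genes had 19 of 37 higher and 28 adjusted over the list alone (adjusted p = 1.28e-10; adjusted p = 0.2 with an estimated correlation). With all libraries none of these lists had a gene past the threshold by limma, with 989 probe sets at an unadjusted p under 0.05. Leaving out libraries by their region markers raises these differences by construction. In the mean over regions, tight junction genes had 3 of 28 lower in germ-free mice, Cldn2 and Cldn4 among them, and the list did not pass (adjusted p = 0.295).

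In single libraries, the pancreatic trypsinogen probe set named for Prss2 reached 7539 in the library labelled conventional jejunum 3, 3218 in that labelled germ-free corpus 3, 3255 in germ-free descending colon 3, 2693 in conventional descending colon 2, 2316 in germ-free jejunum 2, 957 in germ-free jejunum 3 and 785 in germ-free descending colon 2. Elsewhere it was at most 227, and at 1.70 in the library labelled conventional rectum 1. Acta1 was at 1094 in conventional descending colon 3, and Car1 at 1433 in germ-free corpus 2.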
